A study of Homo sapiens with 6 samples.

How the data were processed

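Guide abundance was measured by sequencing guide inserts amplified from genomic DNA in 2 rounds of PCR, per the labels, in 6 libraries: a screen control, a library labelled sorted for MHC class II without IFN and a library sorted with IFN for each of MOLM13 and OCI-AML3. The submitters' processing notes name bcl2fastq, cutadapt and Bowtie2 without versions or settings. The deposited files hold raw read counts per guide, with no normalization by the authors; they list guides with at least 1 read and give reads assigned to no guide in a line of their own. Guides that a file did not list were set to 0. Reads assigned to no guide made up 22.4%, 18.8% and 20.2% of reads in the MOLM13 control, sorted without IFN and sorted with IFN, and 20.2%, 49.7% and 52.8% in the OCI-AML3 libraries in the same order, and were left out of all totals. The labels do not say whether the screen controls were sorted, on which day they were taken or whether they received IFN. The treatment notes describe the IFN pulse without exception, so the presence or absence of IFN was taken from the sample titles.

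Groups and comparisons were taken from the titles. Guide names carry a gene symbol and an Ensembl gene identifier, and a gene is each pair of these. Across the 6 libraries, 202164 guides were seen, of which 190530 targeted 20374 genes (median 10 guides per gene, 59 symbols with more than 1 identifier) and 11634 were negative controls (6687 safe-targeting, 4947 named none). The reference table used here held no Ensembl identifiers, so symbols were matched to current ones by name. 17980 genes matched by symbol, 1397 by 1 synonym alone and 997 did not match, and symbols are printed as the files give them. The files name no genome build, and no coordinates are given. The split of the library into sub-libraries is not given in the sources used here, so scaling within sub-libraries was not run.

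For each sorted library against the control of its line, guides with at least 10 control reads were ranked by log2 of sorted over control CPM (counts per 1e+06 guide reads), each plus a pseudocount of 1. The exact guide-rank test is robust rank aggregation over the top 5% of ranks, with an exact one-sided p from the distribution of ordered ranks, tied guides at their worst rank, and Benjamini-Hochberg adjustment over genes with at least 3 tested guides. Genes were called at an adjusted p under 0.05. Enriched guides had a log2 ratio of at least 2 and at least 10 sorted reads. Read shares are percentages of guide reads over all guides of a gene, with 95% Clopper-Pearson intervals, and the floor for 0 reads is 3 reads. Loss of guides was tested from the bottom ranks where a majority of tested guides had a read, which held for the OCI-AML3 library labelled sorted without IFN alone. The same test compared the sorted libraries with and without IFN in each line, from both ends of the ranks. Genes called in both lines were counted with an exact hypergeometric p. Comparisons against the same control share its chance errors. In 10 simulations per line, both sorted libraries were drawn from the same control. There, 0 genes were called in both IFN states, against 1 (RREB1) observed in MOLM13 and 0 in OCI-AML3. The simulations called a mean of 0 genes per state in MOLM13 and 0.1 in OCI-AML3. Their shared count of 0 therefore says little about errors shared through the control.

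The test was tested on simulated data with 50 genes raised at each fold, in libraries that kept as many guides as each real one. The spread of reads over the kept guides was not fitted to the real libraries. In MOLM13 sorted without IFN, 1659 guides of at least 100 reads held 98.9% of guide reads, so real recovery may be lower than simulated. Recovery at 4-fold, 16-fold, 64-fold and 256-fold was 0%, 42%, 96% and 98% for MOLM13 without IFN, 0%, 58%, 100% and 100% for MOLM13 with IFN, and 6%, 80%, 100% and 100% for OCI-AML3 with IFN. For the OCI-AML3 library labelled sorted without IFN it was 100% at every fold. Recovery at 4-fold was thus low in all 3 libraries that had lost most guides, and the effect of depth alone was not tested. False calls numbered 1 for MOLM13 without IFN, 1 for MOLM13 with IFN and 2 for OCI-AML3 with IFN. For the OCI-AML3 library labelled sorted without IFN there were 3. On uniform ranks, 1.02% of sets of 9 guides had an exact p under 0.01. Random sets of 9 negative-control guides were checked in the same way as genes.

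The genes named follow a rule set before the data were examined, as were the comparisons, the lists and all but 2 of the settings varied below. It takes the 15 called genes with the smallest p from each sorted library against its control, every gene called in both lines, the 8 called genes with the smallest p in each direction from each IFN comparison, and from each fixed list every called member or, where none was called, the 2 with the smallest p. CTBP1, RCOR1, KDM1A, FBXO11 and CIITA were taken in every comparison, and some genes that the rule takes are not reported here. Values of TAP1 against the control, of PTPN2 between the MOLM13 sorted libraries, of genes called in 1 library when given for another, and of the genes that differed between the control libraries were chosen after their values were seen. The 21 lists cover the CtBP-CoREST corepressor, SCF-FBXO11 and neddylation, MHC-II transactivation, MHC-II chains and loading, MHC-II surface turnover, IFN-gamma signalling and its inhibitors, PRC2, PRC1, NuRD, NCoR-SMRT, H3K9 and DNA methylation, Menin-MLL and DOT1L, the Mediator kinase module, SAGA, myeloid transcription factors, growth suppressors, sialylation and glycolipids, ribosomal proteins, proteasome subunits and olfactory receptors. List medians of gene log2 ratios were placed among 10000 random lists of the same size matched on control reads. Adjustment over a list alone took each list by itself, with no adjustment over the 21 lists.

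Alternatives changed the pseudocount (0.1 and 5 CPM), the control read minimum (none and 50), scaling (on negative-control guides), the ranks counted (top 1% and top 10%), the test (hypergeometric on the top 1% of guides), the guides used (without the highest-ranked guide of each gene), the depth (the deeper library thinned) and the control (that of the other cell line). For both lines together, an edgeR quasi-likelihood fit with cell line as a term was run, and on simulated data with 200 genes raised 64-fold it recovered 148 with 1 false call. These data were simulated without the loss of guides seen in the sorted libraries, so this recovery need not hold for those libraries. Setting guides under 100 sorted reads to 0, and replacing the OCI-AML3 library labelled sorted without IFN by the control, were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.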

Results

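A pooled genome-wide CRISPR knockout screen was read out as guide counts in MOLM13 and OCI-AML3, 2 acute myeloid leukaemia cell lines that carried Cas9. Per the labels, each line received lentiviral guides of the Bassik human knockout library at an infection multiplicity of 0.3, followed by puromycin at 2 µg/mL for 72 hours from 48 hours after infection. Cells that stained for the MHC class II molecules HLA-DR, HLA-DP and HLA-DQ were sorted at about days 12, 21 and 28. MHC class II presents peptides to helper T cells, and interferon gamma (IFN) induces it through the transactivator CIITA. Each line gave 1 screen control library, 1 library labelled sorted without IFN and 1 library sorted with IFN (25 ng/mL for 48 hours), so that all 6 libraries were single and no group had a replicate. The comparisons ask which knockouts gather among cells with surface MHC class II, with and without IFN. The MOLM13 sorted libraries and the OCI-AML3 library labelled sorted without IFN came from sort 3, and the OCI-AML3 library with IFN from sort 2.

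Guide reads numbered 70357173 in the MOLM13 control, 5081246 in MOLM13 sorted without IFN and 5508751 in MOLM13 sorted with IFN. OCI-AML3 had 28014487 in the control, 12946823 in the library labelled sorted without IFN and 2745473 in the library sorted with IFN. The sorted libraries differed widely in how many guides they kept. Of the 171359 guides tested in MOLM13, 6.35% had a read without IFN and 10.3% with IFN, and of the 190977 guides tested in OCI-AML3, 37.6% had a read with IFN and 99.98% in the library labelled sorted without IFN. The 10 most-read guides held 19.5% of reads in MOLM13 sorted without IFN, 3.60% in MOLM13 sorted with IFN and 0.386% in OCI-AML3 sorted with IFN, against 0.211% and 0.126% in the MOLM13 and OCI-AML3 controls. A guide with 0 reads could have had a share of up to 5.90e-05% (MOLM13 without IFN), 5.45e-05% (MOLM13 with IFN), 2.32e-05% (OCI-AML3 labelled without IFN) or 0.000109% (OCI-AML3 with IFN). Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Because no group had a replicate, each p measures whether the guides of a gene agreed in those 2 libraries, not how much a condition varies.

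**Figure D1:**
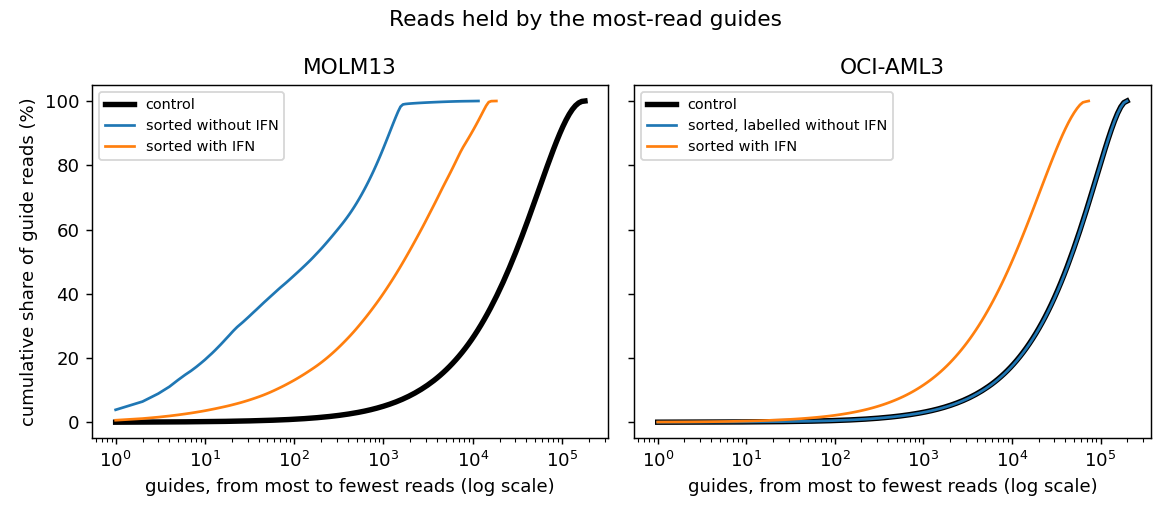
Cumulative share of guide reads (%, vertical axis) against the number of guides ordered from most to fewest reads (horizontal axis, log scale), with 1 line per library in each cell line. The 10 most-read guides hold 19.5% of reads in MOLM13 sorted without IFN, and the OCI-AML3 library labelled sorted without IFN lies on the control curve.

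In MOLM13 sorted without IFN, guides against RREB1 were strongly enriched, and TAPBP was the other gene called. RREB1 (ENSG00000124782), a zinc-finger transcription factor that binds the CtBP corepressor, took 5.09% of guide reads (95% Clopper-Pearson interval 5.07 to 5.11) against 0.00121% in the control, a 4219-fold higher share. 4 of its 8 tested guides were enriched (a log2 ratio of at least 2 with at least 10 sorted reads), and their mean log2 ratio was 5.25 ± 6.58 (SD over 8 guides). The most-read RREB1 guide alone gave 197787 of the gene's 258664 reads. TAPBP (ENSG00000231925), which encodes tapasin of the MHC class I loading complex, had many guides with few reads. 7 of its 9 tested guides had a read, 0 were enriched, and its 115 reads made a share of 0.00226% (0.00187 to 0.00272), 0.526-fold that of the control.

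The exact guide-rank test (one-sided) called 2 of 19568 genes as enriched in MOLM13 sorted without IFN, with 1010 genes at an unadjusted exact p under 0.05 where 978.4 would be expected by chance. The adjusted exact p was 8.83e-07 for RREB1 and 0.00565 for TAPBP. The demethylase KDM1A, its partner RCOR1 and CIITA had 0 reads, against control shares of 0.00432%, 0.00177% and 0.00341%. FBXO11 and CTBP1 had 1 read each, a share of 1.97e-05% (95% interval 4.98e-07 to 0.000110), 0.00890-fold and 0.00487-fold those of the control. Since 6.35% of tested guides had a read in this library and depletion was not tested there, such low counts are no evidence of loss. Of the 7904 guides that counted as top ranks, 4900 had no sorted read and were placed by their control reads alone, as for the olfactory receptor OR4F5 (0 reads, unadjusted exact p 0.00108). RREB1 was called under all 12 alternatives run and TAPBP under 4, not when guides under 100 reads were set to 0 (chosen after the data were seen), and a pseudocount of 0.1 CPM gave 5 called genes, IRF1 and TAP1 among them.

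Among the 21 gene lists fixed beforehand, the CtBP-CoREST corepressor list had 1 of 20 tested members called in MOLM13 sorted without IFN, RREB1, and 1 adjusted over the list alone. The series title names the CtBP complex and FBXO11, so the 2 lists built on them are not independent evidence of their direction. The IFN-gamma signalling list had 0 of 9 members called over all genes tested and 2 when adjusted over the list alone, among them the transcription factor IRF1. IRF1 had a read in 8 of 9 guides with a share 0.475-fold that of the control (adjusted exact p 0.149). The other 19 lists had 0 members called, over all genes tested and adjusted over the list alone, with 52 of their 659 tested members at an unadjusted exact p under 0.05. These were SCF-FBXO11 and neddylation, MHC-II transactivation, MHC-II chains and loading, MHC-II surface turnover, IFN-gamma signalling inhibitors, PRC2, PRC1, NuRD, NCoR-SMRT, H3K9 and DNA methylation, Menin-MLL and DOT1L, the Mediator kinase module, SAGA, myeloid transcription factors, growth suppressors, sialylation and glycolipids, ribosomal proteins, proteasome subunits and olfactory receptors. Most of their members with the smallest p had no enriched guide, and nearly all others had 1. TBL1XR1 of the NCoR-SMRT complex had 1 of 9 guides enriched and a 28.5-fold share, and CDK8 of the Mediator kinase module 1 of 10 and 5.86-fold. CCNC, the cyclin of that module, had 1 of 8 guides enriched and a 22.0-fold share, HLA-DRB5 1 of 7 and 23.8-fold, and HLA-DPA1 1 of 8 and 5.60-fold. In the MHC-II transactivation list the members with the smallest p were RFX5, with 9 reads, and NFYB, with 1 read.

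**Figure D2:**
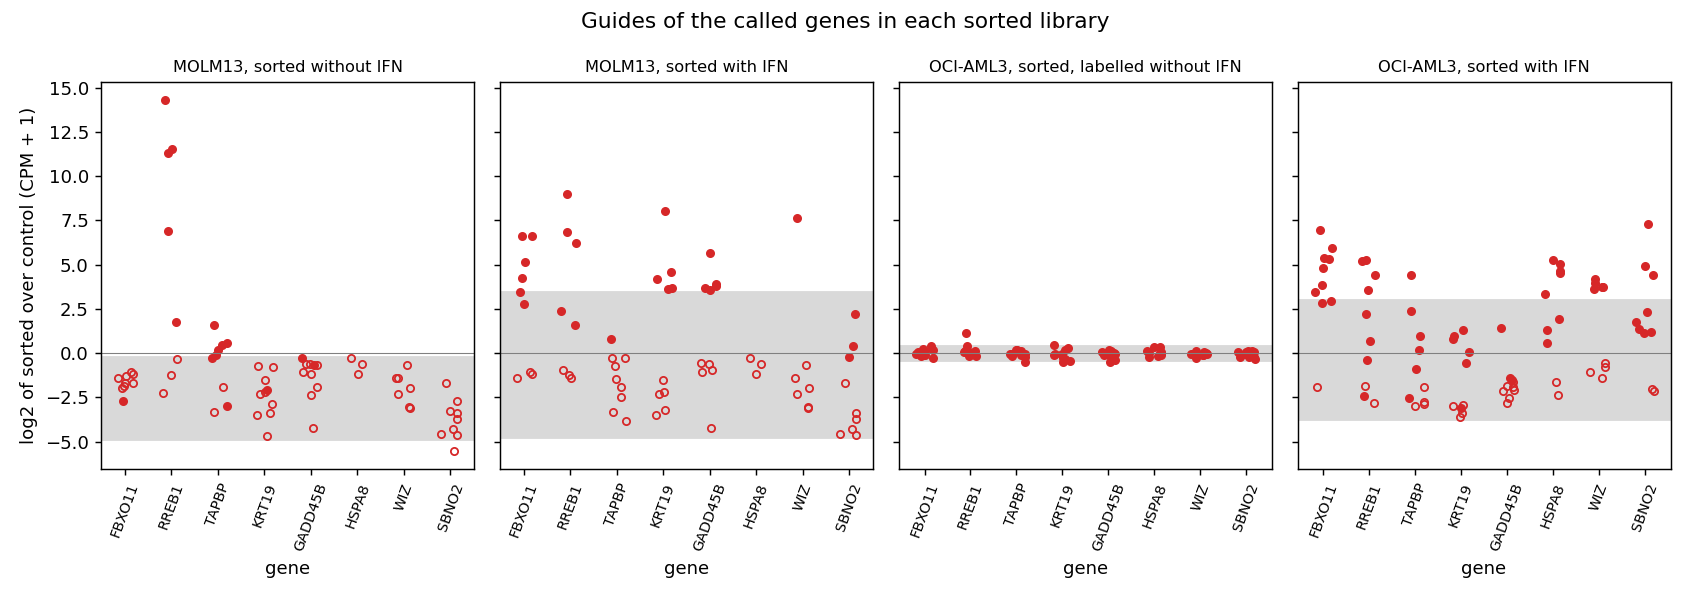
Log2 ratio of sorted over control CPM with a pseudocount of 1 (vertical axis) for every tested guide of the 8 genes called in any sorted library against its control, 1 panel per sorted library. Filled points had a sorted read, open points had none, and the grey band spans the central 95% of negative-control guides; in OCI-AML3 with IFN, 9 of 10 FBXO11 guides are enriched.

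In MOLM13 sorted with IFN, guides against FBXO11, RREB1, KRT19 and GADD45B were enriched. FBXO11 (ENSG00000138081), the substrate receptor of an SCF ubiquitin ligase, had 6 of 9 guides enriched, a mean log2 ratio of 2.81 ± 3.26 (SD over 9 guides) and 0.107% of reads (0.105 to 0.110), 48.5-fold its control share. RREB1 had 4 of 8 guides enriched, a mean log2 ratio of 2.82 ± 4.07 and 0.130% of reads (0.127 to 0.133), a 108-fold share. KRT19 (ENSG00000171345), an intermediate filament keratin of epithelia, had 5 of 10 guides enriched, a mean log2 ratio of 1.14 ± 4.10 and a 99.3-fold share, and 35747 of its 37668 reads came from the most-read guide of the library. GADD45B (ENSG00000099860), a stress-induced growth arrest gene, had 5 of 10 guides enriched, a mean log2 ratio of 1.33 ± 3.18 and an 8.86-fold share.

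By the exact guide-rank test these were 4 of 19568 genes called, with 975 at an unadjusted exact p under 0.05 and 978.4 expected by chance. The adjusted exact p was 0.0174 for FBXO11, 0.0229 for RREB1, and 0.0247 for both KRT19 and GADD45B. CIITA, CTBP1 and KDM1A had 0 reads, in a library where 10.3% of tested guides had a read and depletion was not tested. RCOR1 had 113 reads in 1 of 7 guides and a 1.16-fold share, which did not count as enriched. None of the 4 genes was called when the highest-ranked guide of each gene was left out or when a hypergeometric test on the top 1% of guides was used.

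In the fixed lists for MOLM13 sorted with IFN, CtBP-CoREST had 1 of 20 members called (RREB1) and SCF-FBXO11 and neddylation 1 of 10 (FBXO11), with the same members adjusted over the list alone; both lists follow the series title and are not independent evidence. The IFN-gamma signalling inhibitors had 0 of 12 members called over all genes tested and 1 adjusted over the list alone, PTPN2, a phosphatase that dephosphorylates JAK and STAT proteins. PTPN2 had 2 of 7 guides enriched, a mean log2 ratio of 0.01 ± 4.72 and 0.548% of reads (0.541 to 0.554), a 42.6-fold share, with an adjusted exact p of 0.572 over all genes and 0.00421 over the list. The other 18 lists had 0 members called by either adjustment, with 26 of 646 members at an unadjusted exact p under 0.05. MED13 of the Mediator kinase module had 2 of 10 guides enriched with a 7.88-fold share, the ubiquitin ligase MARCH2 2 of 10 with 9.70-fold, and the histone methyltransferase EHMT2 1 of 9 with 21.5-fold. The polycomb proteins PCGF5 and MTF2 had 2 of 10 and 3 of 9 guides enriched, with shares of 3.22-fold and 2.22-fold. Among MHC-II chains and loading, HLA-DMA had 1 of 7 guides enriched and a 1.65-fold share, and NFYA was the lowest-p member of the MHC-II transactivation list with 1 of 8 and 1.53-fold. The background lists also held such members, as the olfactory receptor OR4C5 had 3 of 7 guides enriched and a 16.0-fold share and the proteasome subunit PSMB7 2 of 6 and 9.80-fold.

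In the OCI-AML3 library labelled sorted without IFN, nearly all tested guides lay near their control level. RREB1 had a mean log2 ratio of 0.18 ± 0.38 (SD over 10 guides), FBXO11 0.04 ± 0.21 and CIITA 0.05 ± 0.22 (9 guides). CTBP1 stood at -0.04 ± 0.28, RCOR1 at -0.04 ± 0.11 and KDM1A at -0.07 ± 0.31. Of the tested guides, 99.9% lay within 2-fold of the control, and the SD of the log2 ratio over guides was 0.22. The exact guide-rank test called 0 of 19815 genes as enriched and 0 as depleted, with 1011 and 1010 genes at an unadjusted exact p under 0.05 and 990.8 expected by chance.

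In the fixed lists for the OCI-AML3 library labelled sorted without IFN, 0 members were called over all genes tested. Adjusted over the list alone, 6 members of 5 lists passed, but each list was adjusted by itself with no adjustment over the 21 lists. For CDKN2A and CDKN2B, 1 guide each stood out, with 28 control reads and 62 in this library, and 38 and 66. The 6 members were the IFN response protease USP18 (mean log2 ratio 0.27 ± 0.51 over 9 guides), HLA-DQA1 (0.27 ± 0.37 over 8), EZH2 (0.08 ± 0.31 over 9), CDKN2A (-0.01 ± 0.60 over 10), CDKN2B (0.09 ± 0.50 over 9) and OR4F5 (0.25 ± 0.64 over 5). The other 16 lists had 0 by either adjustment, with 7 of 268 members at an unadjusted exact p under 0.05. The median log2 ratio of the list of ribosomal proteins was -0.03, at percentile 0.085 of random lists matched on control reads, and that of olfactory receptors 0.02, at percentile 99.5. MHC-II chains and loading lay at percentile 95.1 and SAGA at 1.41.

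In OCI-AML3 sorted with IFN, guides against FBXO11, HSPA8, WIZ, RREB1 and SBNO2 were enriched. FBXO11 had 9 of 10 guides enriched, a mean log2 ratio of 3.96 ± 2.46 (SD over 10 guides) and 0.139% of reads (0.134 to 0.143), 32.3-fold its control share of 0.00429%. HSPA8 (ENSG00000109971), a constitutive chaperone, had 5 of 10 guides enriched, a mean of 2.27 ± 2.76 and a 19.5-fold share. WIZ (ENSG00000011451), a zinc-finger protein that binds CtBP and histone methyltransferases, had 5 of 9 guides enriched, a mean of 1.72 ± 2.55 and a 16.0-fold share. RREB1 had 5 of 10 guides enriched, a mean of 1.39 ± 3.18 and 0.0651% of reads (0.0621 to 0.0681) against 0.00593% in the control, and SBNO2 (ENSG00000064932), a transcriptional coregulator, 4 of 10, a mean of 2.03 ± 2.95 and a 21.8-fold share.

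The exact guide-rank test called these 5 of 19815 genes, with 983 at an unadjusted exact p under 0.05 and 990.8 expected by chance. The adjusted exact p was 1.37e-08 for FBXO11, 0.000332 for HSPA8, 0.000422 for WIZ and 0.0487 for both RREB1 and SBNO2. CTBP1 and CIITA had 0 enriched guides, with shares 0.498-fold and 0.219-fold those of the control (52 and 33 reads). RCOR1 and KDM1A had 1 of 9 guides enriched each, with shares of 1.64-fold and 1.15-fold. Without the highest-ranked guide of each gene, FBXO11, HSPA8 and WIZ were still called and RREB1 and SBNO2 were not.

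Among the fixed lists in OCI-AML3 sorted with IFN, CtBP-CoREST had 2 of 20 members called, RREB1 and WIZ, and SCF-FBXO11 and neddylation 1 of 11, FBXO11, with the same members adjusted over the list alone; again neither list is independent evidence. The IFN-gamma signalling inhibitors had 0 of 12 members called over all genes and 1 adjusted over the list alone, PTPN2, which had 3 of 10 guides enriched and an 8.09-fold share (adjusted exact p 0.935 over all genes and 0.0478 over the list). SOCS1 of the same list had 1 of 10 guides enriched and a 3.65-fold share. The other 18 lists had 0 members called by either adjustment, with 39 of 661 members at an unadjusted exact p under 0.05. IRF9 of the IFN-gamma signalling list had 2 of 10 guides enriched and a 4.98-fold share, the cell cycle inhibitor CDKN1B 3 of 10 and 2.66-fold, and the sialic acid synthesis enzyme GNE 2 of 9 and 3.21-fold. The methyltransferase EHMT1 had 4 of 9 guides enriched with a 1.75-fold share, and its partner EHMT2 1 of 10 with 2.83-fold. MBD2 of NuRD had 2 of 10 guides enriched with a 2.19-fold share, and MTA1 had 1 of 10. The lists below percentile 5 of random lists were MHC-II transactivation (2.15, and 0.05 with means over guides), Menin-MLL and DOT1L (0.19 and 16.0) and H3K9 and DNA methylation (2.53 and 8.38).

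Across the 84 medians of 21 lists in 4 sorted libraries, 8 lay above percentile 95 and 5 below percentile 5 of random lists, where 4.2 would be expected on each side. The list medians come from single libraries and carry no p. In the 3 libraries where most tested guides had no read, gene medians rest mostly on control reads and are no measure of enrichment.

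FBXO11 and RREB1 were called with IFN in both cell lines. Of 19534 genes tested in both, 4 were called in MOLM13 and 5 in OCI-AML3, and the 2 shared genes compare with 0.00102 expected of independent lists (exact hypergeometric p 3.14e-07). FBXO11 had 6 of 9 and 9 of 10 guides enriched, and RREB1 4 of 8 and 5 of 10. KRT19 and GADD45B, called in MOLM13, had 0 of 10 guides enriched each in OCI-AML3 with IFN, and shares of 0.844-fold and 0.119-fold. Of the genes called in OCI-AML3 alone, WIZ had 1 of 7 guides enriched in MOLM13 with IFN and a 21.0-fold share, SBNO2 1 of 9 and 0.656-fold, and HSPA8 0 of 3 with 0 reads. The difference between the cell lines was not tested. Without IFN the lines shared 0 called genes, from 2 in MOLM13 and 0 in OCI-AML3. A single edgeR fit over both lines called 0 of 20279 genes in either state, with 0 genes without IFN and 447 with IFN at an unadjusted p under 0.05. Both counts lie below what chance alone would give, and the state without IFN took in the OCI-AML3 library close to the control. The 0 calls of this fit are therefore no evidence for or against the guide-rank calls. The shared count fell to 1, FBXO11, under 7 of the other settings, to 1, RREB1, with ranks counted in the top 1% alone, and to 0 by the hypergeometric test and without the highest-ranked guide.

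The libraries labelled sorted with and without IFN were compared within each line. In OCI-AML3, where the library labelled sorted without IFN was close to the control, this is not a comparison of IFN alone. There, FBXO11 guides were 31.4-fold higher in share with IFN than in the library labelled sorted without IFN, with 9 of 10 guides enriched and a mean log2 ratio of 3.92 ± 2.45. HSPA8 was 18.5-fold higher, WIZ 16.9-fold, RREB1 9.91-fold and FAM193A (ENSG00000125386) 7.65-fold, with 5 guides enriched each. Since most guides had no read with IFN, only genes abundant in the compared library could be called as lower, and the median of the 10 called genes in the control was 3.54-fold the mean of negative-control guides. CDKN2A, which encodes cell cycle inhibitors, had a share 0.101-fold that of the library labelled sorted without IFN, and the inhibitory G protein subunit GNAI2 0.157-fold. RIC8A, a chaperone of G protein subunits, had 0.0260-fold, and ING1, a chromatin reader, 0.172-fold. MSL2 of a histone acetyltransferase complex, TFPT of the INO80 remodeller and the zinc-finger gene ZNF628 had 1 read each, a share of 3.64e-05% (95% interval 9.22e-07 to 0.000203), with share ratios of 0.00153, 0.00242 and 0.00318.

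The exact guide-rank test called 5 genes as higher and 10 as lower with IFN in OCI-AML3, of 19815, with 991 and 993 at an unadjusted exact p under 0.05. The adjusted exact p of the higher genes was 4.61e-09 for FBXO11, 0.000379 for both WIZ and HSPA8, 0.0267 for RREB1 and 0.0309 for FAM193A. Among the 8 lower genes with the smallest p, the adjusted exact p ran from 8.90e-12 (CDKN2A) to 0.00447 (ING1 and ZNF628). Sort round differed along with IFN in this comparison (2 against 3). With the screen control in place of the library labelled sorted without IFN, an alternative chosen after the data were seen, 5 and 9 genes were called, of which 4 and 9 were the same genes. The exchanged libraries were close to each other, so this overlap is no independent check of the calls.

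In MOLM13, no gene was called as higher with IFN than without, while 5 genes were called as lower, IRF1, RREB1, TAPBP and TAP1 among them. RREB1 had 0.130% of reads with IFN against 5.09% without, a share ratio of 0.0255. TAP1, a subunit of the peptide transporter, had 570 reads against 2027, a ratio of 0.259. This ratio rested on 1 guide, which held 1824 of the 2027 reads without IFN. TAPBP had a read in 1 of 9 guides with IFN and 7 of 9 without, at a share ratio of 0.866, and for IRF1 these were 4 and 8 of 9 guides, while its share was 1.47-fold higher with IFN. The IRF1 call thus rested on how many guides had reads and not on their sum. FBXO11 had 5911 reads with IFN and 1 without, and PTPN2 30163 and 0.

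The exact guide-rank test called 0 of 19568 genes as higher with IFN in MOLM13, with 930 at an unadjusted exact p under 0.05, and the adjusted exact p was 0.0628 for PTPN2 and 0.132 for FBXO11. It called 5 as lower, with 879 at an unadjusted exact p under 0.05. The adjusted exact p was 3.22e-05 for IRF1, 0.000619 for RREB1, 0.00230 for TAPBP and 0.0491 for TAP1. With guides under 100 reads set to 0, RREB1 alone remained lower, but RREB1 was not called without the highest-ranked guide of each gene or by the hypergeometric test.

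**Figure D3:**
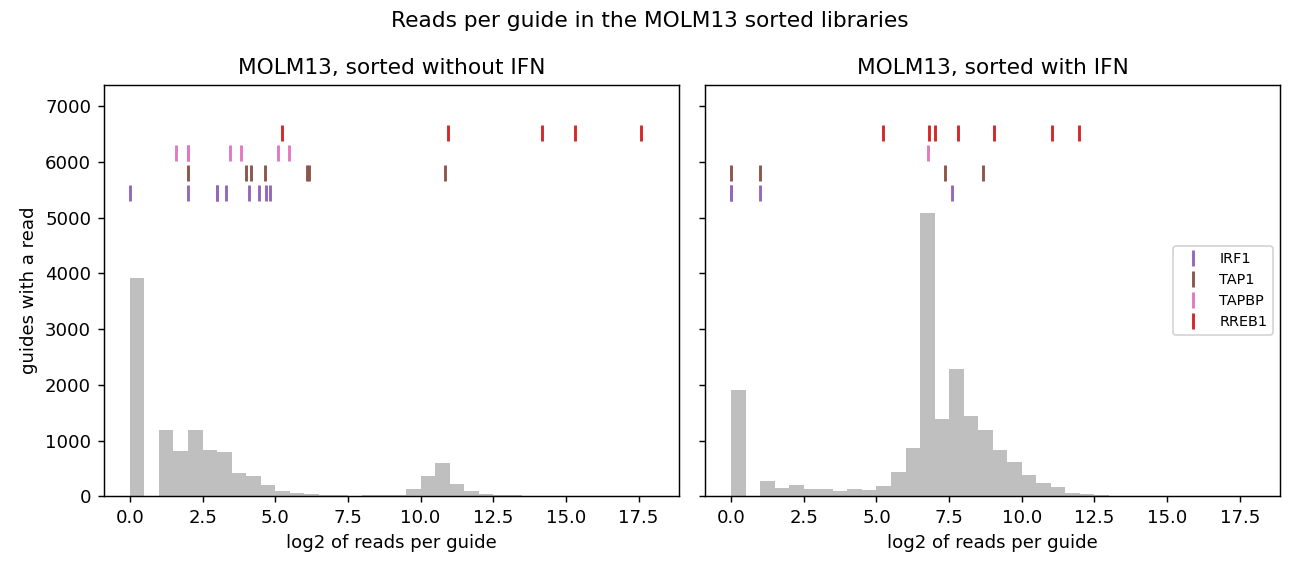
Number of guides (vertical axis) by log2 of their reads (horizontal axis) in the 2 MOLM13 sorted libraries, guides without a read left out. Coloured ticks mark single guides of 4 genes; 23 of 30 guides against IRF1, TAP1 and TAPBP had a read without IFN, and 1 of them had at least 100 reads.

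Guides against genes that every cell needs were scarce in the MOLM13 screen control. In the OCI-AML3 control, ribosomal protein guides had 0.914 and proteasome guides 0.776 of the median of olfactory receptor guides. In the MOLM13 control, guides against 84 ribosomal protein genes had a median of 12 reads (708 guides) against 261 for 11634 negative-control guides, a ratio of 0.0460, and 38.1% of them had no read against 8.09% of negative-control guides. Proteasome guides had a ratio of 0.0517. In the OCI-AML3 control the ratio was 0.445 for ribosomal protein genes (53 against 119 reads) and 0.378 for the proteasome, while 3.81% of ribosomal guides had no read against 4.36% of negative-control guides. Guides against olfactory receptors, genes that blood cells do not need, had ratios of 0.322 in MOLM13 and 0.487 in OCI-AML3, so that the ribosomal ratio was 0.143 and 0.914 with olfactory receptor guides as the reference. The proteasome ratio was then 0.161 and 0.776. The medians of the ribosomal, proteasome and olfactory lists lay at percentile 0 of random lists in both controls, and the plasmid pool was not among the libraries used here.

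Negative-control guides gave the background of each comparison. Enriched guides made up 1.09% of negative-control and 0.922% of gene guides in MOLM13 without IFN, 5.62% and 4.98% in MOLM13 with IFN, and 7.10% and 6.53% in OCI-AML3 with IFN. In the OCI-AML3 library labelled sorted without IFN, 0 guides of either kind were enriched. Of 1128 sets of 9 negative-control guides in MOLM13 and 1188 in OCI-AML3, 0 reached an exact p as low as the called genes where any gene was called, and 2.84% to 7.89% of sets had an exact p under 0.05. The highest shares were 7.89% for higher with IFN in MOLM13 and 7.58% for lower with IFN in OCI-AML3. The lowest was 2.84% in MOLM13 without IFN. On negative-control guides the exact p was thus too small in some comparisons and too large in others. The largest exact p of a called gene ran from 5.77e-07 to 1.77e-05 over the comparisons. So few sets would be unlikely to reach such values, so their count of 0 says little about the calls. Across the 202164 guides seen in any library, the Spearman correlation with the own control was 0.103 for MOLM13 without IFN, 0.167 for MOLM13 with IFN, 0.286 for OCI-AML3 with IFN and 0.976 for the library labelled sorted without IFN, where guides are not independent replicates.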

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

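All tests of explanations in this part, the alternative that sets guides under 100 reads to 0, and the alternative that uses the control in place of the OCI-AML3 library labelled sorted without IFN were chosen only after the results were seen. The differences between sorted libraries with and without IFN were planned.

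Among sorted MOLM13 cells, 5 genes differed between the IFN states, all called from the lower end of the ranks, although the read share of IRF1 was 1.47-fold higher with IFN. Their adjusted exact p values included 3.22e-05 for IRF1, 0.000619 for RREB1, 0.00230 for TAPBP and 0.0491 for TAP1. Over the 11 alternatives run for each, the adjusted exact p ranged from 5.32e-07 to 1 for IRF1, from 0.000349 to 1 for RREB1, from 0.00198 to 1 for TAPBP and from 0.0326 to 1 for TAP1.

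In OCI-AML3 sorted with IFN, 5 genes were higher and 10 lower than in the library labelled sorted without IFN. The adjusted exact p was 4.61e-09 for FBXO11, 0.000379 for WIZ, 0.000379 for HSPA8, 0.0267 for RREB1 and 0.0309 for FAM193A among the higher genes. Over the 11 alternatives run for each, it ranged from 1.76e-09 to 3.98e-06 for FBXO11, from 4.48e-05 to 0.0257 for WIZ, from 0.000271 to 0.0487 for HSPA8, from 0.000550 to 1 for RREB1 and from 0.0212 to 1 for FAM193A, which was called under 5. Among the lower genes it was 8.90e-12 for CDKN2A, 6.46e-09 for GNAI2, 3.64e-05 for RIC8A, 5.42e-05 for MSL2, 0.00175 for TFPT, 0.00447 for ING1 and 0.00447 for ZNF628. The highest adjusted exact p over the alternatives was 0.000533 for CDKN2A, 0.000113 for GNAI2, 0.00648 for RIC8A, 0.00276 for MSL2, 0.0523 for TFPT, 0.501 for ING1 and 0.917 for ZNF628.

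Guides under the control minimum of 10 reads, which entered no test, were chosen for few reads in the control, so that a higher share in any other library follows in part from that choice. They took 4.05% of guide reads in MOLM13 sorted without IFN and 2.25% with IFN, against 0.0475% in the MOLM13 control, and 1.08% in OCI-AML3 sorted with IFN and 0.273% in the library labelled sorted without IFN, against 0.139% in the OCI-AML3 control.

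In MOLM13 sorted without IFN, 23 of 30 guides against the IFN response gene IRF1 and the MHC class I loading genes TAP1 and TAPBP had a read, at medians of 10, 25 and 11 reads, and these 3 genes were called among guides under 100 reads (adjusted exact p 1.21e-05 to 1.31e-05). Selection of these knockouts into the expanded MHC-II+ clones would raise their shares, but 2 of the 3 had shares below the control beyond both 95% intervals, and TAP1 alone lay above it, at 6.26-fold with 1824 of its 2027 reads in 1 guide. Genes without an expanded clone can lie far below the control here, as did FBXO11 (0.00890-fold) and B2M (0.00796-fold). A share below the control therefore does not decide the matter by itself, while IRF1 and TAPBP had 0 guides of at least 100 reads. Reads carried over from the deposited MOLM13 control library are argued against by the count of guides with a read. Of all 20374 genes, 5, these 3 among them, had at least 7 guides with a read. In 1000 shuffles of guides among all genes within bins of control reads, at most 1 gene did (mean 0.001). Of the 3 genes, 0 were called among guides of 100 reads or more, where RREB1 was called. Among guides under 100 reads, 0 of 1128 negative-control sets reached as low an exact p, but so few sets would be unlikely to do so. Reads from a library that is not among these 6 or a small residual cell population may be the source, and they cannot be told apart because neither source is among the libraries used here.

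In OCI-AML3, 9 of the 10 genes lower with IFN lay below the mean of negative-control guides in the sorted library with IFN (median 0.181-fold over the 10 genes), and their median in the control was 3.54-fold that mean, both of which the ranking favours. Negative-control guides are also no neutral level for gene guides, since olfactory receptor guides had 0.487 of their median reads in the OCI-AML3 control. Loss of guides by chance in the sort is argued against by 11 genes chosen on their control reads alone, 7 of which were among the 10. 47 of their 108 guides had a read after sorting with IFN, fewer than in any of 10000 draws of guides matched on control reads (53 to 87 guides). IFN rather than the sort could also underlie the difference, but 9 of the 10 genes were called with the control in place of the library labelled sorted without IFN, so that IFN, the sort and the sort round cannot be told apart without a library sorted without IFN that differs from the control.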

How the results depend on the processing

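Setting guides under 100 sorted reads to 0, and the control in place of the OCI-AML3 library labelled sorted without IFN, were alternatives chosen only after the results were seen. Of the results that answer a comparison, 84 values under an alternative stayed within 1.5 times the reported count and 48 did not. For these 48 the cause was not tested. FBXO11 and HSPA8 in OCI-AML3 with IFN and RREB1 in MOLM13 without IFN were called under every alternative run.

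In MOLM13 without IFN (2 genes), 5 were called with 0.1 CPM as the pseudocount, and 1, RREB1, with at least 50 control reads, the top 1% of ranks, the hypergeometric test, without the highest-ranked guide, with the deeper library thinned, with the other line's control and with guides under 100 reads set to 0. In MOLM13 with IFN (4 genes), 2 were called at 0.1 CPM and 2 with the other control (FBXO11 and PTPN2), 1 at 5 CPM, 1 with at least 50 control reads, 1 with the top 1% of ranks, and 0 by the hypergeometric test or without the highest-ranked guide. In the OCI-AML3 library labelled sorted without IFN (0 enriched), 1 was called at 0.1 CPM, 34 without a filter on control reads, 1 with the top 1% of ranks and 21 with the other control, which also gave 15 depleted genes against 0. In OCI-AML3 with IFN (5 genes), 3 (FBXO11, HSPA8 and WIZ) were called at 0.1 CPM, without a filter, scaled on negative-control guides, without the highest-ranked guide and with the deeper library thinned.

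Higher with IFN in MOLM13 (0 genes) was 1 gene without a filter (FBXO11) and 1 with the top 1% of ranks (PTPN2). Lower with IFN in MOLM13 (5 genes) were 3 with at least 50 control reads, 1 with the top 1% of ranks, 0 by the hypergeometric test, 2 without the highest-ranked guide (RREB1 not among them) and 1 with guides under 100 reads set to 0. In OCI-AML3, the 5 higher genes became 3 at 0.1 CPM and 3 without the highest-ranked guide, and the 10 lower genes 5 without the highest-ranked guide. Genes called in both lines with IFN (2) became 1 at 0.1 CPM, 5 CPM, without a filter, with at least 50 control reads, scaled on negative-control guides, with the top 1% of ranks, with the deeper library thinned and with the other control, and 0 by the hypergeometric test, without the highest-ranked guide and in the edgeR fit. The ribosomal ratio was 0.143 in MOLM13 and 0.914 in OCI-AML3 with olfactory receptor guides as the reference, and the proteasome ratio 0.161 and 0.776. With means over guides, 7 lists lay above percentile 95 instead of 8 and 10 below percentile 5 instead of 5.

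Depletion gave no value in MOLM13 or in OCI-AML3 with IFN, since most tested guides had no read. Scaling within sub-libraries was not run. No paired analysis was possible within a cell line because each group had 1 library, and only the edgeR fit, with cell line as a term, set sorted against control within both lines at once.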

Other observations

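The comparison of the control libraries and all tests of explanations in this part were chosen only after the results were seen.

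The screen controls of the cell lines differed in how abundant some knockouts were. Guides against 16 genes were higher in MOLM13 and against 27 in OCI-AML3 (exact guide-rank test, 19815 genes, 1062 and 1076 at an unadjusted exact p under 0.05), as 1 library of each line was compared with the other. Higher in MOLM13 were the fatty acid synthase FASN (mean log2 ratio 2.92 ± 1.21, SD over 10 guides, adjusted exact p 1.22e-09), the calcineurin B homologue CHP1 (2.40 ± 1.21 over 9) and the lipid acyltransferase AGPAT6 (1.74 ± 1.20 over 10). The aryl hydrocarbon receptor AHR (1.75 ± 2.35) and its partner ARNT (1.81 ± 1.66) were both higher as well, as was the polycomb subunit PCGF1 (1.91 ± 1.10). PTPN2 was called with a mean of 0.54 ± 2.61 and a median of -1.07, so its mean and median differed in sign.

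Higher in OCI-AML3 were guides against the kinase SIK3 (mean log2 ratio of MOLM13 over OCI-AML3 -3.21 ± 0.69 over 10 guides, adjusted exact p 1.05e-08), GNAI2 (-2.77 ± 1.13), the bromodomain protein BRD2 (-2.39 ± 0.68), TSC1 (-2.40 ± 1.63) and CDKN2A (-1.88 ± 1.84). The myeloid transcription factor RUNX1 (-1.79 ± 1.52 over 9) and the signal transducer STAT5B (-2.39 ± 0.80 over 9) were also among them. Medians over that of negative-control guides, in MOLM13 and OCI-AML3 in turn, were 0 and 2.24 for SIK3, 0.502 and 5.92 for GNAI2, and 0.324 and 2.39 for BRD2. They were 0.320 and 3.24 for TSC1, 2.63 and 11.2 for CDKN2A, 0.176 and 1.52 for RUNX1, and 0 and 0.794 for STAT5B. The ratio alone thus does not tell a low level in MOLM13 from a high level in OCI-AML3. Some others called as higher in OCI-AML3 were near the negative-control median there and nearly absent in MOLM13. These included MED29 (0 and 1.27), CDC37 (0.00766 and 1.03) and ELOF1 (0.0249 and 1.06). Ribosomal protein guides stood at 0.143 of the olfactory receptor median in the MOLM13 control and 0.914 in the OCI-AML3 control. Unequal loss of guides between the controls therefore cannot be told apart from a difference between the lines. FLT3, a receptor kinase of myeloid progenitors, did not pass (-2.10 ± 0.93, adjusted exact p 0.124). With the OCI-AML3 library labelled sorted without IFN in place of the OCI-AML3 control, 15 and 22 genes were called, of which 14 and 20 were the same. That library was close to the control it replaced, and the MOLM13 control was kept, so this overlap is no independent check.

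The OCI-AML3 library labelled sorted without IFN was close to its control. The Spearman correlation across guides was 0.976, against 0.103 for the MOLM13 library of the same state, which is consistent with cells not selected behind the label. Selection for surface MHC-II in cells that mostly carry it would remove guides against CIITA, RFX5, RFXAP and RFXANK, but their median log2 ratio was -0.0429 over 38 guides (range -0.70 to 0.62), where -1 or lower was looked for. Reads of 1 library deposited 2 times would give a chi-square per degree of freedom near 1, and it was 1.32 over 188637 guides. This covers repeated reads of the same amplified library, and cannot decide whether another library was prepared from the same cells. Whether the label or the sort accounts for it stays open.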
